A study of Mus musculus with 4 samples.

How the data were processed

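The series holds 4 droplet-based single-cell 3′ gene expression libraries of double-negative thymocytes from mice, grouped by genotype and replicate number as the labels give them. Per the labels, cells bearing CD8α were depleted with beads and lineage-negative cells were sorted before loading. The labels do not say whether the 2 replicates of a genotype came from separate mice, so p-values measure only the spread between these libraries, which may be technical. The labels also describe a nuclear chromatin accessibility preparation, which was not used here.

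The 8 deposited files used were 1 barcode list and 1 feature list per library, both without a header and without any numeric value. Their names call the matrices they belong to raw, that is, not filtered to cells. Per the submitters' processing notes, the genome build was mm10 and the tools were Cell Ranger 3.0.2 and Seurat, with no role or parameters given for either. Counts per gene and barcode were not analysed here. The tests fixed before the data were examined for gene expression, cell types and cell shares were therefore not run, and no threshold on cells or genes was applied. The lists carry no counts, so no depth, counting interval or floor is given.

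Barcodes were read as 16-base strings and each list was checked for repeats, of which there were none. The length of each list was compared between genotypes on the log2 scale by an exact two-sided permutation test over all assignments of the 4 libraries. Sharing was computed for the 6 pairs of libraries as the number of common barcodes over the number expected for independent lists, the product of both lengths divided by the size of the union of the 4 lists. The mean factor of same-genotype pairs was compared with that of different-genotype pairs by an exact permutation of the genotype labels, a test added after seeing the data. A capture-recapture estimate of the pool, the product of both lengths divided by the number shared, was computed for each pair. GC content was averaged over the barcodes of each list. On simulated independent lists from a pool of 400000 barcodes the estimate recovered 100.06% of the pool size. Every simulated barcode had the same chance of being listed, and no barcode pairs were added to these lists. The simulation therefore checks the calculation only, not whether the estimate holds for the real lists. Barcodes differing by the complements of bases 8 and 9 were simulated separately, to check the search for them.

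The 4 feature lists were compared byte for byte. Genes were matched by Ensembl identifier to the GENCODE M21 primary assembly annotation, which is on GRCm38, the build that mm10 denotes. That release may not be the one the submitters used, and 733 matched genes carried another symbol in it. Coordinates are 1-based, from that annotation, and cover the whole gene. An overlap means that the spans of 2 listed genes share at least 1 base, introns included. The rule for named genes put Tcf7 first, then genes by size of change, then fixed lists of genes; with no expression values, Tcf7 and fixed-list members were named for their annotation only. The other genes named are those that overlap them, the receptor constant genes and Lef1os1, which were chosen after the lists were seen.

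The alternatives fixed before the data were examined counted only barcodes listed in exactly 1 library, only those not in all 4, or only those in exactly 2. Others used the capture-recapture pool, a replicate block, and the libraries with each one left out in turn. An alternative that counts as 1 any pair of barcodes differing by the complements of bases 8 and 9 was added after seeing the data. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.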

Results

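The series asks how the dose of TCF1, the transcription factor encoded by Tcf7, bears on the fate of developing T cells. It sets wild-type C57BL/6J mice beside mice of the same strain that carry a genotype named ΔEPE3, and the labels used here do not say what ΔEPE3 removes. The cells were CD4-negative and CD8-negative (double-negative) thymocytes, the immature stages of the thymus that precede expression of CD4 and CD8. They were sorted free of cells bearing TCRβ or markers of B cells, myeloid cells, dendritic cells and erythroid cells. Single-cell 3′ gene expression libraries were made on a droplet platform in which each droplet's RNA receives a bead barcode of 16 bases. There were 4 libraries, 2 wild-type and 2 ΔEPE3. The values analysed here are the list of cell barcodes and the list of annotated genes of each library. Counts of molecules per gene and cell were not analysed here, so no gene has an expression level in either genotype, no cell type has a share, and the depth of each library is unknown.

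All 4 libraries were annotated with the same list of 32285 genes, so the list says nothing about a difference between the genotypes. By gene identifier, 32235 of them matched the GENCODE M21 annotation of GRCm38 (mm10), and 50 did not. Of the matched genes, 21702 were protein-coding, 270 were segments of T cell receptor loci and 427 were segments of immunoglobulin loci. The receptor segments comprised 144 variable genes, 70 joining genes, 4 diversity genes and 8 constant genes, with the rest annotated as pseudogenes.

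Tcf7 (ENSMUSG00000000782) was in the list of every library. In mm10 it is a protein-coding gene on the minus strand of chromosome 11, from 52252371 to 52283014, with 2 annotated transcripts and 13 distinct exons. A further listed gene, A630014C17Rik, overlaps the Tcf7 span on the opposite strand, and no listed gene overlaps it on the same strand. Lef1 (ENSMUSG00000027985), which encodes the related factor LEF1, lies on the plus strand of chromosome 3 from 131110471 to 131224356, and Lef1os1 overlaps it on the opposite strand.

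The genes fixed for this comparison were nearly all annotated: 104 of 106 distinct genes in 20 lists were present by the symbol used. All 22 genes of the T commitment list were there. They include Gata3, a transcription factor of early T cell development (chromosome 2, 9857078 to 9890034, minus strand), and Bcl11b, which is needed for T lineage commitment (chromosome 12, 107910403 to 108003602, minus strand). They also include Il2ra, which encodes CD25 (chromosome 2, 11642807 to 11693193, plus strand), and Ptcra, which encodes the pre-T cell receptor alpha chain (chromosome 17, 46755663 to 46763712, minus strand). The 12 progenitor genes, 14 innate lymphoid and NK cell genes, 8 B cell genes, 11 myeloid and dendritic cell genes, 8 cycling genes and 5 Wnt target genes were also all present. Among these, Kit, a receptor of early progenitors, spans 75574916 to 75656722 on chromosome 5. Id2, a transcriptional regulator of innate lymphoid cells, spans 25093799 to 25097140 on chromosome 12.

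Of the 10 γδ T cell genes, 8 were present by symbol. The missing symbols were Trgc1 and Trgc2. The other 18 of the 20 lists, among them the markers of double-negative stages, mast cells, erythroid cells and stroma, were complete. The list carries the γ constant genes under the names Tcrg-C1, Tcrg-C2, Tcrg-C3 and Tcrg-C4 on chromosome 13, between 19214103 and 19352756. Trdc, the δ constant gene, was present at 54142851 to 54148868 on chromosome 14, and Trac, the α constant gene, at 54220521 to 54224206 on the same chromosome. The β constant genes Trbc1 and Trbc2, which are near-identical copies, were listed as separate genes on chromosome 6.

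Some of the fixed genes share their position with other annotated genes. Gata3 and Rag1 each overlap a listed gene on the same strand, 9230102O04Rik for Gata3 and B230118H07Rik for Rag1, and 29 of the 104 overlap one on the opposite strand. The share over all listed genes was not computed, so these counts cannot be called high or low. Rag1 and Rag2 encode the recombinase that cuts antigen receptor genes, and B230118H07Rik overlaps Rag2 on the opposite strand.

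The barcode lists were compared next, because of the lists analysed here they alone differ between the libraries. The wild-type lists held 3190168 barcodes in replicate 1 and 3109624 in replicate 2, a mean of 3149896 ± 56953 (SD, n = 2). The ΔEPE3 lists held 3228248 barcodes in replicate 1 and 2482929 in replicate 2, a mean of 2855588 ± 527020 (SD, n = 2). The ratio of the geometric means, ΔEPE3 over wild type, was 0.899, a log2 ratio of -0.15. The difference was smaller than the spread within the ΔEPE3 group, where the lists differed by 745319 barcodes, or 26.1% of their mean. The wild-type lists differed by 80544 barcodes, or 2.56% of their mean. An exact permutation test of the log2 list lengths gave a two-sided p = 1.0, with 0.333 the smallest p that 2 libraries against 2 allow. The direction rested on ΔEPE3 replicate 2, without which the log2 ratio was 0.036. The direction also turned, to 0.21, for barcodes listed in exactly 1 library, a number that depends on the other lists too. It was kept, at -0.34, for barcodes not listed in all 4, where the same 1508099 barcodes leave every list. The lists belong to matrices that were not filtered to cells, so their length is not a number of cells. The depth of each library is unknown, so an effect of depth on list length cannot be told apart from one of genotype.

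**Figure D1:**
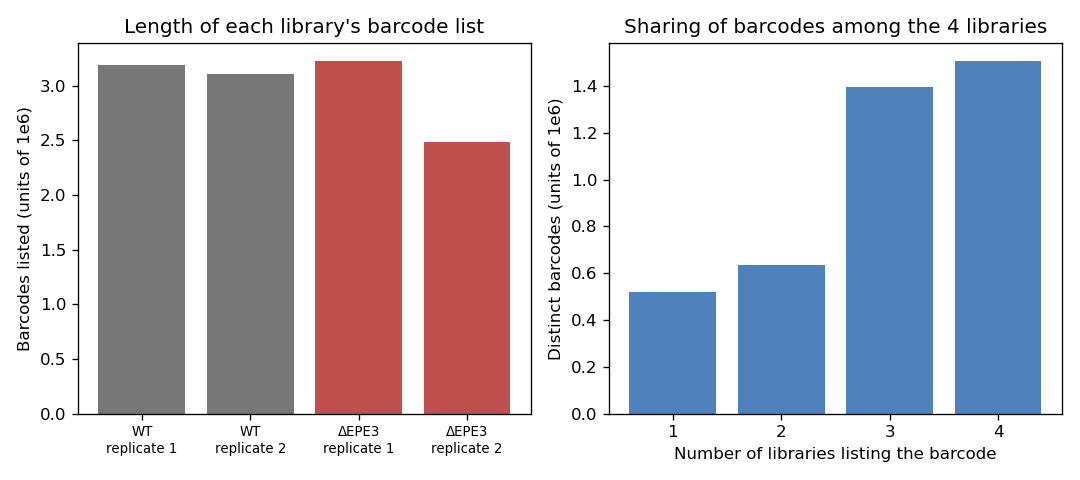
Left, the number of barcodes (linear axis from 0, in units of 1e6) in each library's list, with wild-type libraries in grey and ΔEPE3 libraries in red; each bar is 1 library and carries no error bar. Right, the number of distinct barcodes (in the same units) by how many of the 4 libraries list them; ΔEPE3 replicate 2 has the shortest list, at 2482929 barcodes, and 1508099 barcodes are in all 4.

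The 4 lists drew on a common set of barcodes. Together they held 4059216 distinct barcodes, of which 1508099 (37.2%) were in all 4 lists, 1396294 (34.4%) in 3, 634868 (15.6%) in 2 and 519955 (12.8%) in 1. Each pair of libraries shared more barcodes than independent draws from that union would, by a mean factor of 1.04 ± 0.00827 (SD over 6 pairs, which are not independent). The size of the factor depends on the pool assumed, which here was the union of the same 4 lists. The factor was 1.01 when barcodes differing by the complements of bases 8 and 9 were counted once, and lay between 1.00737 and 1.01666 when any one library was left out and the union taken over the other lists. For barcodes listed in exactly 2 libraries it was 0.677, below the number independent lists would place in those 2 alone. The wild-type pair shared 2581965 barcodes, 1.06 times the independent value, and the ΔEPE3 pair shared 2038652, 1.03 times. With barcodes differing by those complements counted once the order turned, at 1.0083 for the wild-type pair and 1.0152 for the ΔEPE3 pair. The mean factor was 1.04 for pairs of the same genotype and 1.04 for pairs of different genotypes. The difference between these means, same minus different genotype, was 0.000434. Every library enters both means with equal weight, so effects of single libraries largely cancel. Near-equal means therefore carry little information on genotype. An exact two-sided permutation test over the 3 splits of the libraries into 2 pairs gave p = 1.0, with 0.333 the smallest p possible. The mean GC content of the listed barcodes was 49.7% ± 0.0204 (SD, n = 4 libraries), and every barcode held 5 to 11 G or C bases.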

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

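The log2 ratio of list lengths, ΔEPE3 over wild type, was -0.15, and no setting run could have brought its exact permutation p under the threshold. Its sign turned to 0.21 when barcodes listed in exactly 1 library were counted, and it was -0.34 for barcodes not listed in all 4 libraries. The ratio was -0.16 with barcode pairs at bases 8 and 9 counted once. With each library left out in turn it ranged from -0.34 (without ΔEPE3 replicate 1) to 0.036 (without ΔEPE3 replicate 2). The replicate block gave -0.15, the same value by construction, with 0.02 for replicate number 1 and -0.32 for number 2. The numbers could not be shown to pair the libraries. The mean factor by which pairs of lists overlapped beyond independence, 1.04, was 1.00 (0.999622) with the pool set to the median capture-recapture estimate, as that construction requires. That estimate, 3886036, lay below the union of 4059216, so it is not a size of the pool. The mean factor was 0.677 for barcodes listed in exactly 2 libraries, set against the number that independent lists of the full lengths would place in those 2 alone, and the cause was not tested. It was 1.01 with barcode pairs counted once. With each library left out it was 1.00737 to 1.01666, computed on the smaller union of 3 lists. GC content was 49.6% for barcodes listed in exactly 1 library, against 49.7%; the cause was not tested. No other annotation release or symbol match was tried for the gene lists. The alternatives planned for expression, cell classes and cell shares were not run because counts were not analysed here.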

Other observations

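The test in this part was chosen after its result was seen. Barcodes listed in a single library mostly differed from another listed barcode only at bases 8 and 9. Of the 519955 such barcodes, 80.2% had a partner in the union of the lists that differed by the complements of bases 8 and 9, counted from 1 at the 5′ end. The share was 30.1% among barcodes listed in all 4 libraries. A partner could be in any library, and its presence in the same library was not computed for single-library barcodes. Each pair counts for both its members, so these shares are not independent. At bases 10 and 11, the other adjacent position with most partners, the shares were 15.4% and 17.5%. Over all barcodes, 36.6% had a partner at bases 8 and 9, none had one at bases 7 and 8 or at 9 and 10, and the remaining positions lay between 11.7% and 17.2%. A candidate explanation is that each bead of this chemistry carries a second barcode version, related to the first by its middle bases, which enters the list less often. No read was examined here, and no biological explanation was tested.

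Counting each such pair once left 3316975 barcodes in the union. The pairwise pool estimates then ran from 3258983 to 3294810, against 3842121 to 3931770 for all barcodes. Each range lay below its own union, which held 3316975 with pairs counted once and 4059216 before pairs were merged. A pool cannot be smaller than the barcodes listed from it, so independent listing with equal chance did not hold. These estimates are therefore not sizes of the pool. The share of a library's barcodes whose partner was in the same list was 19.2% and 19.8% in the wild-type libraries and 21.9% and 18.0% in the ΔEPE3 libraries, so the genotypes overlapped. The longest list had the highest share and the shortest list the lowest, though the longer wild-type list had the lower share of its group. The shares were not adjusted for list length.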
